A study of Homo sapiens with 30 samples.

How the data were processed

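RNA sequencing was performed on 6 lymphocyte subsets from frozen blood mononuclear cells that were thawed, rested overnight without added cytokines, stained and sorted by flow cytometry, per the labels' protocols. The labels give 4 natural killer (NK) subsets that were CD3-negative and CD56dim, divided by CD57 and NKG2C, and 2 CD8 T cell subsets divided by CD57. A sample code recurs once in every subset, and the series title speaks of donors, so the 6 libraries of 1 code were taken as 1 donor. This gave 5 donors, 6 groups and 30 libraries. Donors are numbered 1 to 5, and the replicate number of a library is the number of its donor. The libraries were made with a TruSeq RNA version 2 kit, per the labels' protocols, which does not mark strand.

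The authors deposited a table of whole-number read counts per gene symbol and a table of FPKM values (fragments scaled to gene length and depth) for the same samples. Per the submitters' processing notes, STAR 2.4.0d, featureCounts, Subread 1.4.5-p1, R 3.2.0 and limma were used with the builds GRCh37 and hg19. The notes give no role or order for these tools. The gene annotation, the strand setting, the treatment of reads that map to several places and the tool behind the deposited FPKM values are not given in the sources used here. The count table held 26363 genes, 26257 genes were in the table of FPKM values, and 26226 were in both. Every column carried the label of exactly 1 sample. No coordinates were used. The human reference at hand was of another build, and its annotation served only for exon lengths in the closing section.

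Counts were used as deposited. Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with robust estimation, TMM factors, the filterByExpr defaults and the donor as a block. The 20 NK libraries were fitted together (13225 genes tested) and the 10 T cell libraries together (12331 genes tested). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05. Adjusted p-values of genes are from this edgeR test, and values after "±" on a log2 fold change are standard errors. Levels are CPM (counts scaled to library size) with the SD over 5 libraries. Gate genes, marker sums and the levels in the closing section use totals scaled by TMM over all 30 libraries. Levels set beside a fold change use TMM-scaled totals of the NK or the T cell fit. The comparisons, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

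The donor block was used because the subsets of a donor are repeated samples of 1 person. The pairing was checked on log2 CPM deviations from the group means. The 75 pairs of libraries from the same donor had correlations of at least 0.134, with a median of 0.647. The median was -0.196 over 300 pairs from different donors. No libraries agreed within sampling noise: the smallest chi-square per degree of freedom between libraries was 15.8 within groups (60 pairs) and 4.03 across groups (375 pairs).

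Total counts per library ranged from 4788541 to 18462118, and 14628 to 22841 genes had at least 1 read. Counts were also simulated, and 13080 genes were tested for late adaptive against late canonical cells. Changes of 1.5-fold, 2-fold and 4-fold were given to 67, 67 and 66 genes. The test called 43.3%, 83.6% and 93.9% of these. It called 12 of 12880 unchanged genes, beside 29, 56 and 62 changed ones. For the T cell comparison (12151 genes) these shares were 16.4%, 58.2% and 95.5%, with 14 of 11953 unchanged genes called. In both, most of the genes given a 1.5-fold change were missed. The shares called per fold change describe only the genes given a change, which were drawn above a low-count bound, not all genes tested.

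The 32 gene lists covered genes reported as high or low in adaptive NK cells, NK maturation, T cell states, metabolism, stress and signalling, receptors, cytokines, transcription and chromatin regulators, and markers of other blood cells. They were tested with limma 3.58.1. The camera test, which compares a list with all other genes, was run with a preset correlation between genes of 0.01 and again with a correlation estimated per list. The fry test asks whether a list's genes move on balance 1 way and was kept as a side calculation. Adjusted p-values of lists are from camera with the preset correlation unless an estimated correlation is named, adjusted over the lists within a comparison. Lists with fewer than 3 tested members were not tested as lists. Some lists share genes: all late NK maturation genes but SPON2 are also on the effector T cell list. The mitochondrially encoded respiratory chain and the gamma delta T cell markers were not analysed here. Besides the count over all genes tested, the count with p-values adjusted over the list alone is given.

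Genes named in the text met a fixed rule. They were among the 10 largest increases or decreases per comparison that passed the test, had a mean of at least 5 CPM and moved the same way in all 5 donors, or they were members of a list, or they encode or make the proteins of the sort gates. ARID5B was named in every comparison. Y-linked genes, XIST, HLA and KIR genes, receptor segments and clone identifiers were left out of the ranked part. Exceptions are stated where they occur. Some genes that met the rule are not reported here. Reads of near-identical genes could have been split in counting, so values of KLRC1 to KLRC4, XCL1 and XCL2, CCL3 and CCL4 with their copies, FCGR3A, HSPA1A and the KIR genes are uncertain. Genes that overlap on opposite strands could not be told apart.

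Alternatives were DESeq2-type size factors, upper-quartile factors, no low-count filter, a filter of 1 CPM in 5 libraries, no donor block, each donor left out in turn, all 30 libraries in 1 fit, only the 2 groups compared, limma-voom, the DESeq2 1.42.0 Wald test, limma on log2(FPKM + 0.1) with and without a filter at a mean FPKM of 0.5, limma on log2(FPKM + 1), an adjusted p under 0.01 and a log2 fold change of at least 1. Other alternatives were chosen after seeing the data: B cell and monocyte marker scores as covariates, leaving out late adaptive replicate 3, leaving out early adaptive replicate 4, and thinning every library to the smallest total. The marker scores were the mean log2 CPM of each list. Group values were checked for a library apart from the others of its group by Dixon's ratio, with a critical value of 0.71 for 5 samples.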

Results

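Messenger RNA was profiled in 4 NK cell subsets and 2 CD8 T cell subsets from the same 5 donors, with 5 libraries per subset. The NK subsets crossed CD57, a glycan that marks late maturation, with NKG2C, an activating receptor carried by the adaptive NK cells that expand with cytomegalovirus infection. They are called late adaptive (CD57+NKG2C+), late canonical (CD57+NKG2C-), early adaptive (CD57-NKG2C+) and early canonical (CD57-NKG2C-). The T cell subsets were effector memory (CD45RA+CD57+) and naive (CD45RA+CD57-). Total counts ranged from 7328730 to 13388950 in late adaptive, 4788541 to 15545129 in late canonical and 5677963 to 18462118 in early adaptive libraries. They ranged from 5908266 to 16439818 in early canonical, 7251512 to 17171208 in effector memory and 7436452 to 17074188 in naive libraries. Between 14628 and 16794 genes had a read in 29 of the libraries, and 22841 in late adaptive replicate 3. The series title names canonical and adaptive NK cells and CD8 T cells, so the comparisons ask how adaptive NK cells differ from canonical ones, how CD57 stages differ, and whether the differences resemble those between effector memory and naive T cells.

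Genes of the gate proteins were examined first, as a check of the labels. KLRC2, which encodes NKG2C, averaged 385 ± 92.9 CPM (SD, n = 5) in late adaptive and 338 ± 87.3 in early adaptive libraries, against 40.7 ± 29.4 in late canonical and 36.0 ± 13.7 in early canonical libraries. B3GAT1, the glucuronyltransferase that makes the CD57 epitope, averaged 124 ± 69.2 CPM in late adaptive, 102 ± 58.4 in late canonical, 99.8 ± 26.0 in effector memory, 3.04 ± 2.80 in early canonical and 1.22 ± 1.20 in naive libraries. In the early adaptive libraries, sorted as CD57-negative, it averaged 56.3 ± 42.0 CPM (range 8.04 to 97.2). NCAM1 (CD56) averaged 103 to 126 CPM across the NK groups, 6.33 ± 5.62 in effector memory and 0.404 ± 0.351 in naive cells. CD8A averaged 1853 ± 426 CPM in effector memory and 822 ± 172 in naive cells, and 100 to 145 in the NK groups. CD8B averaged 362 ± 115 and 555 ± 187 CPM in the T cell groups and at most 4.77 ± 5.70 in an NK group. CD3E, whose surface complex the NK gate excluded, averaged 368 ± 116 CPM in late adaptive, 218 ± 80.8 in early adaptive, 85.2 ± 110 in late canonical and 59.0 ± 45.0 in early canonical cells, against 649 ± 74.8 and 848 ± 271 in effector memory and naive T cells. PTPRC (CD45) averaged 2574 to 3956 CPM in the 6 groups, and CD4 at most 16 ± 21.7.

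Transcripts of other blood cells differed between the NK sorts. The summed B cell markers (among them MS4A1, CD79A and PAX5) averaged 815 ± 595 CPM in early canonical libraries (range 136 to 1438), 100 ± 137 in early adaptive, 38.4 ± 21.2 in late canonical and 14.0 ± 6.23 in late adaptive libraries. Monocyte markers (among them CD14, LYZ and S100A8) averaged 1301 ± 2247 CPM in early adaptive (range 8.53 to 5218), 668 ± 695 in early canonical, 90.1 ± 146 in late canonical and 61.2 ± 78.3 in late adaptive libraries. Dendritic cell markers averaged 75.6 ± 24.9 CPM in early canonical and 23.2 ± 19.6 in early adaptive, against 14.1 ± 6.76 and 3.31 ± 2.05 in late canonical and late adaptive libraries. Markers of innate lymphoid cells other than NK cells averaged 139 ± 72.9 CPM in early canonical, 68.8 ± 45.5 in early adaptive and at most 15.4 ± 4.51 in the late groups. T cell markers averaged 318 ± 88.5 CPM in late adaptive, 246 ± 15.8 in late canonical, 242 ± 83.5 in early adaptive and 141 ± 38.7 in early canonical libraries, against 1193 ± 238 and 1709 ± 228 in the effector memory and naive T cells.

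**Figure D1:**
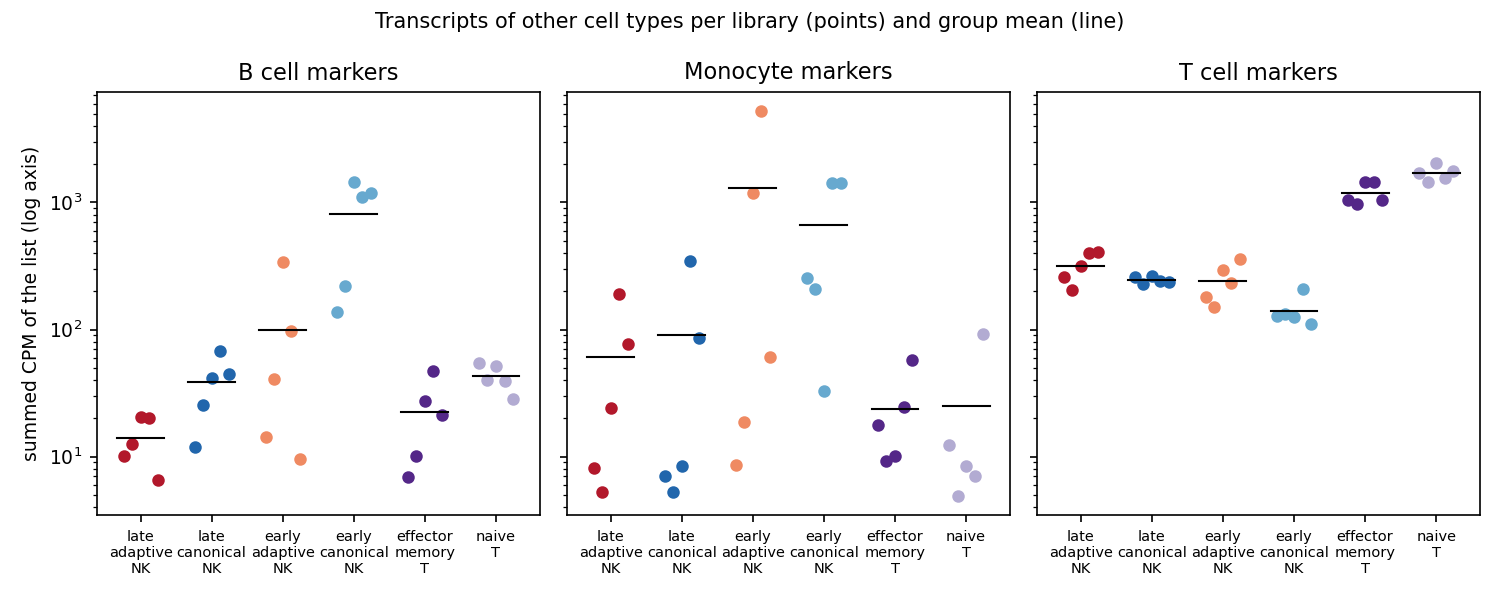
Summed expression of B cell, monocyte and T cell marker genes (CPM, log axis) in each library, with 1 point per library and a line at the group mean, for the 6 sorted groups of 5 libraries. B cell markers lay between 136 and 1438 CPM in the early canonical NK libraries and at or below 20.5 CPM in the late adaptive ones, while monocyte markers ranged from 8.53 to 5218 CPM within the early adaptive group.

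Late adaptive cells were compared with late canonical cells to ask how adaptive cells differ at the same CD57 stage. Of 13225 genes, 283 rose and 368 fell in late adaptive cells (651 changed, against 2504 at an unadjusted p under 0.05 and 661 expected by chance), 103 and 160 of them by at least 2-fold. CD3E rose by 3.02 ± 0.73 log2 units (adjusted p = 0.031) and UBASH3A, a phosphatase-like regulator of T cell receptor signalling, by 4.05 ± 0.68 (adjusted p = 0.0053), both in 5 of 5 donors. LAG3, an inhibitory receptor, rose by 3.26 ± 0.69 (adjusted p = 0.016), from 26.6 ± 26.2 to 219 ± 229 CPM. KLRC1, which encodes the inhibitory receptor NKG2A, fell by 3.36 ± 0.45 (adjusted p = 0.0017), from 111 ± 58.4 to 10.7 ± 7.72 CPM.

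**Figure D2:**
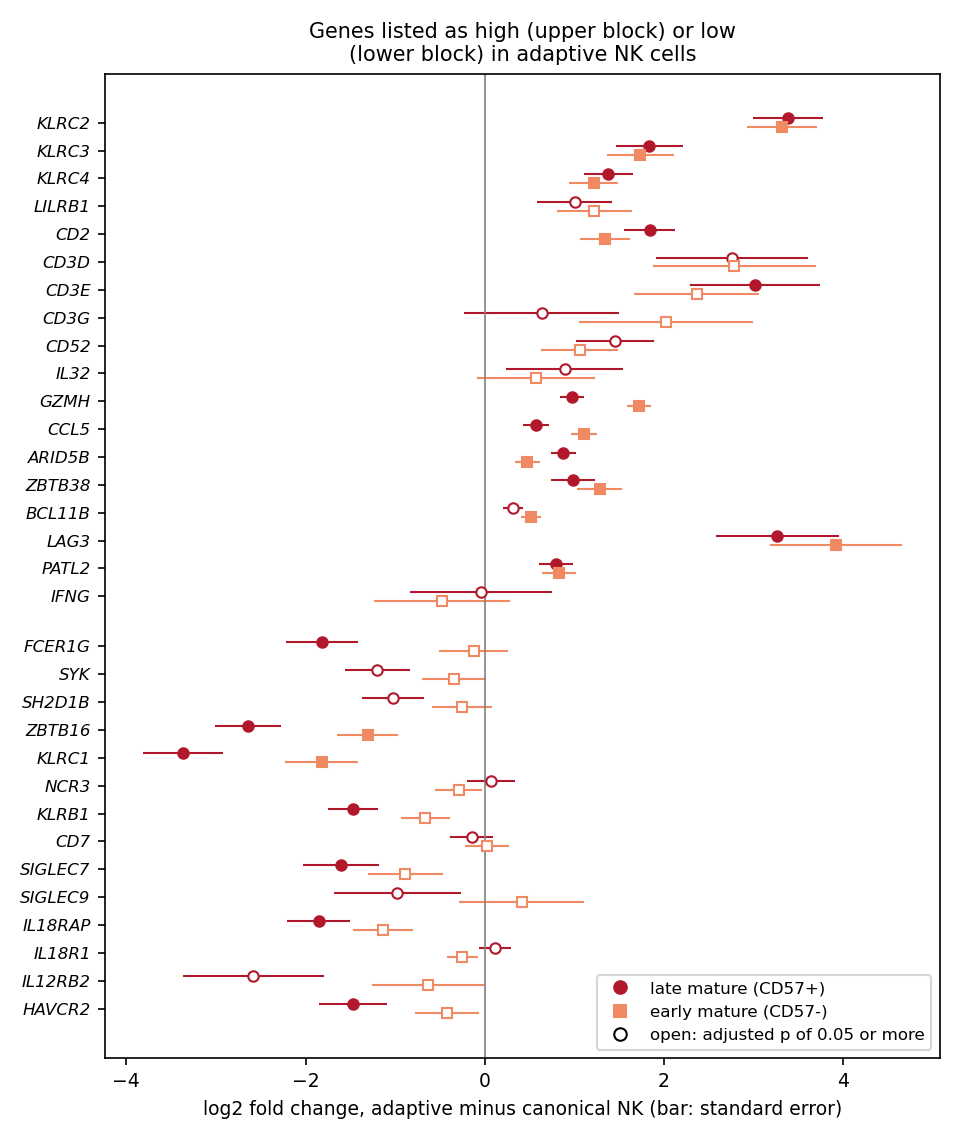
Log2 fold changes (adaptive minus canonical NK cells, n = 5 donors) of the genes listed as reported high (upper block) or low (lower block) in adaptive NK cells, with bars for the standard error, circles for the late mature and squares for the early mature comparison, and open symbols where the adjusted p was 0.05 or more. In each comparison 11 of the 18 genes of the upper block rose, while 7 of the 14 genes of the lower block fell in the late and 2 in the early comparison. The upper block holds KLRC2, the gene of the NKG2C gate.

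Of the 18 genes reported as high in adaptive NK cells, 11 rose, none fell and 7 did not pass the test (15 rose adjusted over the list alone, camera adjusted p = 3.9e-21, adjusted p = 0.020 with an estimated correlation). KLRC2, the gene of the NKG2C gate, is on this list and rose by 3.38 ± 0.39. The sort set its direction in each adaptive against canonical comparison, so its rise is only a check of the labels. The adhesion receptor CD2 rose by 1.84 ± 0.29, the granzyme GZMH by 0.97 ± 0.13, the transcription factor ZBTB38 by 0.98 ± 0.25 and the chemokine CCL5 by 0.57 ± 0.15. ARID5B, a DNA-binding partner of a histone demethylase, rose by 0.88 ± 0.14 (adjusted p = 0.0024, higher in 5 of 5 donors), from 48.8 ± 16.2 to 88.6 ± 19.2 CPM. The study singled out ARID5B and the respiratory chain subunit UQCRB in these libraries, so neither is independent evidence of its direction. Of the 14 genes reported as low, 7 fell and 7 did not pass (10 fell adjusted over the list alone, camera adjusted p = 1.2e-12, adjusted p = 0.033 with an estimated correlation). Besides KLRC1 these were the transcription factor ZBTB16 (-2.64 ± 0.37), the Fc receptor adapter FCER1G (-1.82 ± 0.40), the cytokine receptor chain IL18RAP (-1.85 ± 0.35) and the receptors KLRB1 (-1.47 ± 0.28), SIGLEC7 (-1.6 ± 0.43) and HAVCR2 (-1.47 ± 0.37). SYK, a kinase on this list, had a log2 fold change of -1.2 ± 0.36 that did not pass (adjusted p = 0.077).

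NK receptors outside the KIR family moved in both directions, with 5 of 31 higher and 4 lower (adjusted over the list alone 5 rose and 6 fell, camera adjusted p = 0.97). Of 28 lymphocyte transcription factors, ZBTB38 and IKZF1 rose and ZBTB16, BACH2 and NFIL3 fell (adjusted over the list alone 6 rose and 4 fell, camera adjusted p = 0.85). Of 22 proximal signalling genes, CD3E and LCK (0.63 ± 0.13) rose and FCER1G and the kinase TXK (-0.65 ± 0.12) fell. Among 20 chromatin and DNA methylation regulators, ARID5B and the Polycomb protein CBX7 (0.52 ± 0.12) rose, and 2 fell, among them the DNA methyltransferase DNMT3A (-0.52 ± 0.12). The receptors S1PR1 and ITGB1 rose, by 0.46 ± 0.10 and 0.66 ± 0.16, and the integrin ITGAE fell by 1.4 ± 0.24. Of the cytokine receptors, IL18RAP and IL2RB fell, 2 of 21 (camera adjusted p = 0.044). That call was lost with an estimated correlation (adjusted p = 0.69). Of 78 nuclear-encoded respiratory chain genes, UQCRB alone rose, by 0.45 ± 0.07 (adjusted p = 0.0034, 5 of 5 donors). The list's median change was 0.11 (camera adjusted p = 0.00058, adjusted p = 0.77 with an estimated correlation). Of 19 interferon-stimulated genes 1 rose, OASL by 0.56 ± 0.11, and 1 fell, with 8 lower adjusted over the list alone (camera adjusted p = 1.1e-05, adjusted p = 0.47 with an estimated correlation). The list of late NK maturation genes did not move as a group (1 of 14 fell, SPON2, -1.59 ± 0.38, camera adjusted p = 0.97). Of 10 HLA class II genes 1 rose (4 adjusted over the list alone, camera adjusted p = 1.3e-06, adjusted p = 0.47 with an estimated correlation). Of 21 effector T cell genes GZMH and CCL5 rose (camera adjusted p = 0.31) and 2 of 11 naive T cell genes fell (camera adjusted p = 0.63). The calls of the adaptive-high and adaptive-low lists were the only ones in this comparison that held with an estimated correlation. The adaptive-low call was then lost without late adaptive replicate 3 or early adaptive replicate 4 (adjusted p = 0.051 in each). Both were lost with the B cell and monocyte marker scores as covariates (adjusted p = 0.096 with an estimated correlation), where the medians were 1.23 and -1.55, against 0.99 and -1.47 without the covariates, and camera adjusted p with the preset correlation was 4.3e-15 and 5.2e-10. That fit called 869 genes, among them 500 of the 651. No member of the KIR family (8 tested), the early NK maturation list (13) or the glycolysis, sterol synthesis, heat shock, cell cycle or BCL2 family lists passed, of 20, 15, 12, 15 and 13 tested.

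B cell and monocyte markers had no member that passed in this comparison (0 of 10 and 0 of 11). Summed dendritic cell markers averaged 3.31 ± 2.05 CPM in late adaptive and 14.1 ± 6.76 in late canonical libraries. Without donor 2, 3, 4 or 5 the comparison called 211, 153, 166 and 417 genes, without late adaptive replicate 3 it called 372, and with no donor block 9. Of the 46 genes taken by the naming rule that passed, 11 passed without each donor in turn: KLRC2 (the gate gene), CD2, GZMH, ARID5B, UQCRB, OASL, ZBTB16, KLRC1, ITGAE, SCRN1 (-3.95 ± 0.50) and TNFRSF25 (-3.44 ± 0.52).

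Early adaptive cells were compared with early canonical cells to ask the same question before CD57 is acquired. Of 13225 genes, 505 rose and 438 fell (943 changed, 3122 at an unadjusted p under 0.05), 109 and 206 by at least 2-fold. With upper-quartile scaling 396 rose and 486 fell. B3GAT1 rose by 4.23 ± 0.51 log2 units (adjusted p = 0.00085) although both groups were sorted as CD57-negative. LAG3 rose by 3.92 ± 0.74, the adhesion molecule CADM1 by 3.15 ± 0.40 and the Fc receptor gene FCGR3A by 1.32 ± 0.19, each in 5 of 5 donors. The lymph node homing receptor CCR7 fell by 2.89 ± 0.47 (adjusted p = 0.0036), from 229 ± 187 to 27.6 ± 23.8 CPM. The largest decreases included B cell genes such as FCRL1 (-4.90 ± 0.78), TCL1A (-4.09 ± 0.72) and EBF1 (-4.08 ± 0.75), beside summed B cell markers of 100 ± 137 CPM in early adaptive and 815 ± 595 in early canonical libraries.

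Of the 18 genes reported as high in adaptive cells, 11 rose (15 adjusted over the list alone, camera adjusted p = 1.8e-22, adjusted p = 0.012 with an estimated correlation), among them GZMH by 1.72 ± 0.14, CCL5 by 1.11 ± 0.15, ZBTB38 by 1.28 ± 0.25 and BCL11B, a transcription factor of T cell development, by 0.52 ± 0.12. Of the 47 genes taken by the naming rule that passed, 23 passed without each donor in turn, and ARID5B was not among them. ARID5B rose by 0.47 ± 0.14 (adjusted p = 0.045, 4 of 5 donors). UQCRB rose by 0.41 ± 0.07 (adjusted p = 0.0036), and as above neither is independent evidence. Of the 14 genes reported as low, ZBTB16 (-1.31 ± 0.34) and KLRC1 (-1.82 ± 0.41) fell (3 fell adjusted over the list alone, camera adjusted p = 0.0039, adjusted p = 0.26 with an estimated correlation). FCER1G did not pass at this stage (-0.12 ± 0.38, adjusted p = 0.89). With totals scaled over all 30 libraries, it ranged from 38.5 to 261 CPM in early adaptive libraries, where monocyte marker sums ranged from 8.53 to 5218. A share of FCER1G from other cells was not tested, so these values do not show whether early adaptive NK cells keep it. Of 14 late NK maturation genes 7 rose (9 adjusted over the list alone, camera adjusted p = 3.4e-10, adjusted p = 0.038 with an estimated correlation), among them B3GAT1, the chemokine receptor CX3CR1 (1.2 ± 0.25) and the transcription factors PRDM1 (0.94 ± 0.12), ZEB2 (0.69 ± 0.14) and TBX21 (0.33 ± 0.09). Effector T cell genes rose with them, 10 of 21 (13 adjusted over the list alone, camera adjusted p = 1.2e-18, adjusted p = 0.012 with an estimated correlation). All 7 late maturation genes that rose are also on the effector list. Of 28 transcription factors 7 rose, among them KLF2 (1.03 ± 0.25), and 4 fell: ZBTB16, BACH2 (-0.76 ± 0.20), TOX2 (-2.26 ± 0.39) and ID3 (-2.07 ± 0.46), with camera adjusted p = 0.071 (median 0.15, mean -0.05). NK receptors had 7 of 31 higher and 1 lower (camera adjusted p = 0.0021, adjusted p = 0.12 with an estimated correlation), and 3 of 15 sterol synthesis genes fell, HMGCS1 (-0.59 ± 0.16) among them (camera adjusted p = 0.0027, adjusted p = 0.32 with an estimated correlation). Respiratory chain genes had UQCRB and NDUFS5 (0.49 ± 0.13) higher, 2 of 78 (camera adjusted p = 7.4e-05, adjusted p = 0.57 with an estimated correlation).

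All 10 tested B cell markers fell in early adaptive cells, MS4A1 (-3.78 ± 0.61) among them, and this list's call held with an estimated correlation (camera adjusted p = 2.7e-15, adjusted p = 0.027). Monocyte markers had no member that passed (0 of 11), with sums of 1301 ± 2247 CPM in early adaptive libraries (5218 in replicate 4) and 668 ± 695 in early canonical ones. Of 3 dendritic cell and 3 innate lymphoid markers 1 each fell (camera adjusted p = 0.0039 and 0.020, adjusted p = 0.12 and 0.23 with an estimated correlation). Their sums averaged 23.2 ± 19.6 and 68.8 ± 45.5 CPM in early adaptive and 75.6 ± 24.9 and 139 ± 72.9 in early canonical libraries. With the B cell and monocyte marker scores as covariates edgeR called 0 genes, with 2294 at an unadjusted p under 0.05, and no other tool was run with them. With no donor block the count was 22, without donors 3 and 4 it was 349 and 452, and with only these 2 groups fitted 284. In the covariate fit the median of the adaptive-high list was 1.59, against 1.25 without the covariates, and its call was lost with an estimated correlation (adjusted p = 0.35). The late maturation and effector T cell calls were lost in the same way (adjusted p = 0.44 and 0.35), with medians of 0.59 and 0.63 against 0.55 and 0.43 without the covariates. With the preset correlation these 3 lists still passed (camera adjusted p = 1.2e-07, 0.00060 and 6.9e-06), and the adaptive-low list did not (median -0.69 against -0.38, camera adjusted p = 0.22).

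The difference of the 2 adaptive comparisons was tested directly, late minus early. ALPK2, an alpha kinase outside the naming rule and chosen after its values were seen, was the only gene of 13225 that passed (5.38 ± 0.72, adjusted p = 0.014, 5 of 5 donors, with 1043 genes at an unadjusted p under 0.05). It averaged 3.11 ± 3.28 CPM in late adaptive, 0.167 ± 0.228 in late canonical, 1.94 ± 1.5 in early adaptive and 5.20 ± 5.27 in early canonical cells. Among lists, late NK maturation genes had a median difference of -0.51 (camera adjusted p = 1.8e-13, adjusted p = 0.020 with an estimated correlation), effector T cell genes -0.49 (camera adjusted p = 8.2e-17, adjusted p = 0.017 with an estimated correlation) and the KIR family, taken as a group, -1.28 (camera adjusted p = 0.00011, adjusted p = 0.020 with an estimated correlation). Beside them the B cell markers had a median difference of 2.45 (camera adjusted p = 7.2e-10, adjusted p = 0.079 with an estimated correlation). With the B cell and monocyte marker scores as covariates the KIR family had a median of -0.62 and did not pass (camera adjusted p = 0.16). The late maturation and effector lists had medians of -0.83 and -0.61 there, and both calls were lost with an estimated correlation (adjusted p = 0.45 in each). The adaptive minus canonical median of the late maturation list was -0.0019 in late and 0.55 in early cells, and that of the KIR family -0.34 and 0.72. B3GAT1 had a difference of -4.03 ± 0.63 that did not pass (adjusted p = 0.092), and ARID5B had one of 0.40 (adjusted p = 0.64). The genes reported as low in adaptive cells had a median difference of -0.83 (camera adjusted p = 1.5e-05, adjusted p = 0.11 with an estimated correlation), so a dependence on stage was not established for that list. The count of 1 was 0 with edgeR with no donor block (266 at an unadjusted p under 0.05), without donor 2, 4 or 5 and without late adaptive replicate 3. It was 0 with limma-voom (902 at an unadjusted p under 0.05), 67 with DESeq2, 3 without donor 1 and 2 without early adaptive replicate 4. ALPK2 was also not called with all 30 libraries in the fit, after thinning or with the marker scores as covariates.

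Late canonical cells were compared with early canonical cells to describe maturation outside the adaptive lineage. Of 13225 genes, 752 rose and 1122 fell (1874 changed, 3681 at an unadjusted p under 0.05), and 127 and 697 did so by at least 2-fold. FGFBP2 rose by 1.93 ± 0.32 log2 units, GZMH by 1.62 ± 0.14, and PRF1 and GZMB, which encode cytotoxic granule proteins, by 0.89 ± 0.19 and 0.79 ± 0.22. The chemokine receptors CX3CR1, CXCR1 and CXCR2 rose by 1.96 ± 0.25, 3.27 ± 0.63 and 2.0 ± 0.35. CCR7 went from 229 ± 187 to 8.11 ± 11.5 CPM (-5.21 ± 0.54), and the interleukin-7 receptor IL7R (-3.82 ± 0.93), the stem cell factor receptor KIT (-3.77 ± 0.63) and GZMK (-3.09 ± 0.72) fell as well. These changes had the same sign in 5 of 5 donors. Summed B cell and monocyte markers differed beside them, from 815 ± 595 to 38.4 ± 21.2 and from 668 ± 695 to 90.1 ± 146 CPM.

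Of 14 late maturation genes 12 rose (13 adjusted over the list alone, camera adjusted p = 3.9e-20, adjusted p = 0.0065 with an estimated correlation), and of 13 early maturation genes 11 fell (12 adjusted over the list alone, camera adjusted p = 2.2e-11, adjusted p = 0.020 with an estimated correlation). Effector T cell genes rose in 17 of 21 cases (17 adjusted over the list alone, camera adjusted p = 1.6e-25, adjusted p = 0.0032 with an estimated correlation) and 7 of 11 naive T cell genes fell (9 adjusted over the list alone, camera adjusted p = 3.3e-08, adjusted p = 0.0085 with an estimated correlation). All late maturation genes but SPON2 are also on the effector list, so their rises are not separate results. Both lists hold B3GAT1, which makes the CD57 epitope of the sort. Of 28 transcription factors 10 rose, among them TBX21 (0.68 ± 0.09), ZEB2 (0.68 ± 0.14), PRDM1 (1.09 ± 0.12), MAF (1.01 ± 0.21) and RUNX3 (0.35 ± 0.08), and 7 fell, among them TOX2 (-6.12 ± 0.56), ID3 (-4.79 ± 0.58), RUNX2 (-4.13 ± 0.53) and TCF7 (-2.03 ± 0.53), with camera adjusted p = 0.19 (median 0.23, mean -0.50). Of 21 cytokine receptors 4 rose and 5 fell, IL12RB2 (-2.35 ± 0.67) and IL18R1 (-0.84 ± 0.18) among the latter, and of 24 trafficking receptors 6 rose and 6 fell (camera adjusted p = 0.32 and 0.77). Cytokine genes had 3 of 20 higher and 5 lower, among them XCL1 (-2.72 ± 0.48) and XCL2 (-1.63 ± 0.42), with camera adjusted p = 0.33. The largest increases also held PDGFRB, a growth factor receptor (3.07 ± 0.36), and SLC1A7, a glutamate transporter (3.77 ± 0.67). Immediate early genes fell in 4 of 16 cases, EGR1 (-2.74 ± 0.73) and NR4A1 (-2.09 ± 0.45) among them (camera adjusted p = 0.0028, adjusted p = 0.33 with an estimated correlation), heat shock genes in 3 of 12 (camera adjusted p = 0.0049, adjusted p = 0.30 with an estimated correlation) and sterol synthesis genes in 5 of 15 (camera adjusted p = 0.0073, adjusted p = 0.36 with an estimated correlation). Proximal signalling genes rose in 4 of 22 cases (camera adjusted p = 0.0013, adjusted p = 0.16 with an estimated correlation), and genes reported as high in adaptive cells in 4 of 18 (camera adjusted p = 9.9e-05, adjusted p = 0.23 with an estimated correlation). ARID5B did not pass (-0.16 ± 0.14, adjusted p = 0.50).

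All 10 tested B cell markers fell (camera adjusted p = 7.2e-16, adjusted p = 0.031 with an estimated correlation), MS4A1 (-5.45 ± 0.69) and CD22 (-6.37 ± 0.84) among them, with JCHAIN (-7.31 ± 0.70) and BCL11A (-7.19 ± 0.86) among the largest decreases. HLA class II genes, which B cells and monocytes express highly, fell in 9 of 10 cases (camera adjusted p = 2.1e-14, adjusted p = 0.041 with an estimated correlation), their regulator CIITA, among them (-2.37 ± 0.48). Of 11 monocyte markers, LYZ (-5.00 ± 1.26) and MNDA (-4.07 ± 1.05) fell, and 11 fell adjusted over the list alone (camera adjusted p = 0.00034, adjusted p = 0.34 with an estimated correlation). All 3 tested markers of innate lymphoid cells fell, KIT among them (camera adjusted p = 4.2e-05, adjusted p = 0.051 with an estimated correlation), as did all 3 dendritic cell markers (adjusted p = 0.080 with an estimated correlation). With the B cell and monocyte marker scores as covariates edgeR called 0 genes, with 1555 at an unadjusted p under 0.05, and no other tool was run with them. With no donor block it called 243, and without donors 3, 4 and 5 it called 1248, 1016 and 1089. In the covariate fit the median change was 1.25 over the late maturation genes and -0.91 over the early ones, against 0.91 and -2.03 without the covariates. Both calls were lost there with an estimated correlation (adjusted p = 0.15 and 0.48). So were those of the effector T cell list (median 0.79 in both fits, adjusted p = 0.15) and the naive T cell list (-0.58 against -1.61, adjusted p = 0.48). The HLA class II list did not pass with either correlation (-0.44 against -2.60, camera adjusted p = 0.23, adjusted p = 0.91 with an estimated correlation).

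Late adaptive cells were compared with early adaptive cells to follow the CD57 stages within the adaptive lineage. Of 13225 genes 29 rose and 243 fell (272 changed, 2280 at an unadjusted p under 0.05), 2 and 188 of them by at least 2-fold. GZMH rose by 0.88 ± 0.13 log2 units, PRDM1 by 0.56 ± 0.12, BCL11B by 0.46 ± 0.11 and TTC16, the largest increase within the naming rule, by 1.08 ± 0.20, each in 5 of 5 donors. KIT (-4.67 ± 0.74), the oxysterol receptor GPR183 (-4.75 ± 0.63), the interleukin-12 receptor chain IL12RB2 (-4.29 ± 0.79) and TOX2 (-5.07 ± 0.71) fell. FCER1G also fell (-2.24 ± 0.40), from 124 ± 89.8 to 24.6 ± 11.8 CPM. A share of its early adaptive level from other cells was not tested. Early maturation genes fell in 5 of 13 cases (9 adjusted over the list alone, camera adjusted p = 3.1e-14, adjusted p = 0.022 with an estimated correlation), XCL1 (-2.98 ± 0.48) and CCR7 (-3.1 ± 0.58) among them, and naive T cell genes in 3 of 11 (7 adjusted over the list alone, camera adjusted p = 1.2e-08, adjusted p = 0.022 with an estimated correlation). Of 14 late maturation genes 1 rose (5 adjusted over the list alone, camera adjusted p = 3.5e-07, adjusted p = 0.072 with an estimated correlation). Effector T cell genes had 2 of 21 higher (7 adjusted over the list alone, camera adjusted p = 1.6e-08, adjusted p = 0.062 with an estimated correlation). Of the transcription factors BCL11B and PRDM1 rose and TOX2, RUNX2 (-2.75 ± 0.51), BACH2 (-1.21 ± 0.21) and IRF8 (-1.96 ± 0.40) fell (median 0.14, mean -0.43, camera adjusted p = 0.83). DNMT3A (-0.59 ± 0.12) and the hexokinase HK2 (-3.04 ± 0.60) fell. ARID5B did not pass (0.24 ± 0.13, adjusted p = 0.38), nor did B3GAT1 (1.32 ± 0.38, adjusted p = 0.093).

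Other-cell transcripts differed in this comparison too. Monocyte markers averaged 61.2 ± 78.3 CPM in late adaptive and 1301 ± 2247 in early adaptive libraries, and no member passed over all genes (11 of 11 fell adjusted over the list alone, adjusted p = 0.29 with an estimated correlation). Of 10 B cell markers 3 fell, MS4A1 (-3.64 ± 0.82) among them (camera adjusted p = 9.6e-07, adjusted p = 0.16 with an estimated correlation). Innate lymphoid markers, KIT among them, averaged 15.0 ± 4.32 CPM in late adaptive and 68.8 ± 45.5 in early adaptive libraries, and 1 of 3 tested fell (camera adjusted p = 0.00018, adjusted p = 0.072 with an estimated correlation). Dendritic cell markers averaged 3.31 ± 2.05 and 23.2 ± 19.6 CPM, and 1 of 3 fell (camera adjusted p = 0.010, adjusted p = 0.16 with an estimated correlation). The count of changed genes was 65 without early adaptive replicate 4, which held the highest monocyte marker sum, 123 without late adaptive replicate 3, and 3 with no donor block and with the marker scores as covariates. It was 98, 7, 46, 27 and 678 without donors 1 to 5 in turn, 50 with limma-voom, 150 with no low-count filter, 151 on log2(FPKM + 1) and 829 with DESeq2. With only these 2 groups fitted 96 rose and 189 fell, and without donor 5 these counts were 127 and 551. None of the 29 genes that rose was called again without donor 2, without donor 4 or with no donor block. Of the 32 genes taken by the naming rule that passed, 3 passed without each donor in turn: IGFBP4, TOX2 and TNFSF14. In the covariate fit the early maturation and naive T cell calls held with an estimated correlation (adjusted p = 0.033 in each), with medians of -1.06 and -1.04 against -1.74 and -1.48 without the covariates.

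Effector memory and naive CD8 T cells were compared as the T cell counterpart of maturation. Of 12331 genes, 2198 rose and 2286 fell in effector memory cells (4484 changed, 5894 at an unadjusted p under 0.05 against 617 expected by chance), 951 and 1034 by at least 2-fold. GZMH rose by 5.54 ± 0.32 log2 units (from 15.1 ± 15.5 to 563 ± 279 CPM), GZMB by 5.11 ± 0.36, GNLY by 4.33 ± 0.57 and PRF1 by 3.57 ± 0.49, as did CX3CR1 (6.06 ± 0.42) and the transcription factors ZNF683 (5.67 ± 0.60), ZEB2 (4.16 ± 0.51) and TBX21 (3.23 ± 0.48). The homing receptor CCR7 (-4.87 ± 0.78), the transcription factors LEF1 (-4.27 ± 0.38) and TCF7 (-2.73 ± 0.37) and the BMP antagonist NOG (-6.25 ± 0.72) fell. All of these had adjusted p of 0.00425 or lower and the same sign in 5 of 5 donors. The share of reads from the ribosomal RNA gene RNA45S5, a measure of library quality, was 0.634 to 1.93% in naive and 0.237 to 0.597% in effector memory libraries, and it was higher in naive cells in 5 of 5 donors.

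Effector T cell genes rose in 20 of 21 cases (21 adjusted over the list alone, camera adjusted p = 2.1e-34), late NK maturation genes in 14 of 14 (camera adjusted p = 3.5e-29) and NK receptors in 21 of 30 (22 adjusted over the list alone, camera adjusted p = 1.3e-16), among them LILRB1 (4.90 ± 0.32), NCR1 (4.74 ± 0.39), TIGIT (2.53 ± 0.41) and PDCD1 (1.91 ± 0.27). Each of these 3 lists had an adjusted p = 0.11 with an estimated correlation. All late maturation genes but SPON2 are also on the effector list, so the rises of those lists are not separate results. Both hold B3GAT1, which makes the CD57 epitope of the sort. Naive T cell genes fell in 12 of 13 cases (13 adjusted over the list alone, camera adjusted p = 1.6e-11, adjusted p = 0.25 with an estimated correlation). Genes reported as high in adaptive NK cells rose in 12 of 18 cases (13 adjusted over the list alone, camera adjusted p = 4.4e-10, adjusted p = 0.054 with an estimated correlation), KLRC2 by 2.77 ± 0.25 and ZBTB38 by 1.66 ± 0.18. ARID5B rose by 1.31 ± 0.13 (adjusted p = 0.0010, 5 of 5 donors), from 36.1 ± 9.27 to 88.3 ± 17.0 CPM. HLA class II genes rose in 9 of 10 cases, CIITA by 3.37 ± 0.41 (camera adjusted p = 3.9e-08, adjusted p = 0.11 with an estimated correlation). Of 26 transcription factors 15 rose and 7 fell, with TOX (2.98 ± 0.25), IKZF2 (2.51 ± 0.22) and EOMES (2.99 ± 0.31) higher and BACH2 (-2.48 ± 0.32) lower (camera adjusted p = 0.011, adjusted p = 0.39 with an estimated correlation). Of 19 cytokines 10 rose and 4 fell, CCL4 by 3.59 ± 0.35 and the death ligand FASLG by 3.8 ± 0.59 among the first and LTB (-4.21 ± 0.68) among the second (camera adjusted p = 0.0065, adjusted p = 0.25 with an estimated correlation). Trafficking receptors had 10 of 23 higher and 2 lower (camera adjusted p = 0.00035, adjusted p = 0.21 with an estimated correlation).

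Beside this difference in ribosomal RNA, of 78 respiratory chain genes 35 fell and none rose in effector memory cells (38 fell adjusted over the list alone, camera adjusted p = 3.8e-07, adjusted p = 0.51 with an estimated correlation), among them COX7C (-1.45 ± 0.33), NDUFV2 (-1.4 ± 0.31), COX4I1 (-1.35 ± 0.24) and UQCRB (-0.67 ± 0.21, adjusted p = 0.042). Glycolysis genes had 9 of 20 lower, LDHB (-2.41 ± 0.27) and HK2 (-3.02 ± 0.41) among them, and 2 higher, among them the glucose transporter SLC2A1 (0.97 ± 0.24), with camera adjusted p = 0.035 (adjusted p = 0.39 with an estimated correlation). Heat shock genes fell in 6 of 12 cases (camera adjusted p = 0.0028, adjusted p = 0.43 with an estimated correlation). Of 14 BCL2 family genes 5 rose and 1 fell, with BCL2L11 higher (1.15 ± 0.28) and BCL2 lower (-1.32 ± 0.19), and camera adjusted p = 0.37. In this comparison no list held its call with an estimated correlation. Leaving out a donor gave 3096 to 3640 changed genes and omitting the donor block 3352.

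Late adaptive cells were compared with early canonical cells, which differ in both CD57 and NKG2C, to set NK and T cell differentiation side by side. Of 13225 genes 1486 rose and 1897 fell (3383 changed, 4988 at an unadjusted p under 0.05), 297 and 968 by at least 2-fold. GZMH rose by 2.60 ± 0.14, SGCD, a sarcoglycan, by 4.81 ± 0.39, CADM1 by 3.92 ± 0.41 and ARID5B by 0.72 ± 0.14 (adjusted p = 0.0012). FCER1G fell by 2.36 ± 0.41. Of the adaptive-high list 14 of 18 rose (15 adjusted over the list alone, camera adjusted p = 8.4e-20, adjusted p = 0.019 with an estimated correlation) and of the adaptive-low list 10 of 14 fell (10 adjusted over the list alone, camera adjusted p = 3.7e-07, adjusted p = 0.065 with an estimated correlation). All 10 B cell markers fell as well, MS4A1 (-7.42 ± 0.79) among them, beside summed B cell markers of 14.0 ± 6.23 and 815 ± 595 CPM and monocyte markers of 61.2 ± 78.3 and 668 ± 695 CPM. With the marker scores as covariates 1 of the 18 adaptive-high genes rose, with a list median of 2.51 against 1.67 without them (camera adjusted p = 2.4e-09). That call was lost with an estimated correlation (adjusted p = 0.33). The count was 849 with no donor block, 1951 with only these 2 groups fitted and 6 with the marker scores as covariates.

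Over the 12124 genes tested in both cell types, fold changes in late adaptive minus early canonical NK cells and in effector memory minus naive T cells correlated across genes at r = 0.458 and rho = 0.310, where genes are not independent replicates. Of the genes that rose in the NK comparison 627 also rose in the T cells, against 262 for independent lists, and 650 fell in both, against 268. Opposite calls numbered 97 and 133, against 257 and 274. GZMH, ZBTB38 and ARID5B were among the genes higher in both. With no low-count filter r was 0.130. With late adaptive minus late canonical cells as the NK side it was 0.150 (rho = -0.00695), with 112 genes higher in both against 49.8 for independent lists and 104 lower in both against 54.1. With late canonical minus early canonical cells it was 0.435.

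**Figure D3:**
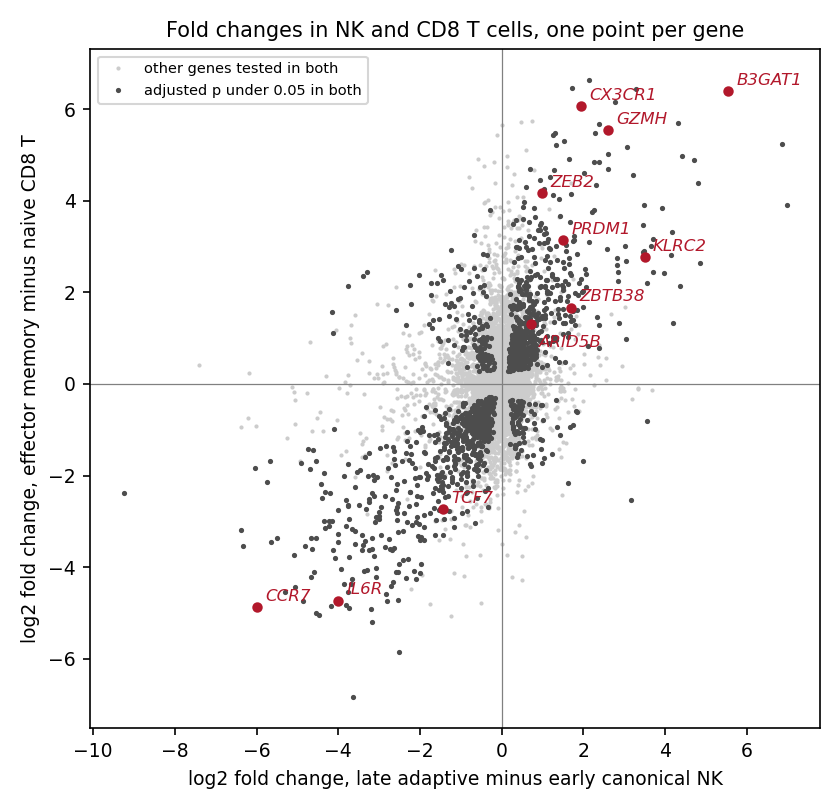
Log2 fold changes of 12124 genes in late adaptive minus early canonical NK cells (x axis) and in effector memory minus naive CD8 T cells (y axis), with 1 point per gene, dark where both adjusted p-values were under 0.05, and selected genes labelled. The labelled genes lie in the upper right or lower left, and across genes r was 0.458.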

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

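The test of T cells as the source of CD3E and the fit with marker scores as covariates were chosen only after results had been seen. For that fit the counts of genes had been seen when its predictions were written, and the medians had not. The bootstrap interval on the early maturation list was added after its value had been seen, and it changed the reading of that value from a fit to an open one.

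Lower expression in late than in early canonical NK cells covered 1122 genes, and B cell and monocyte markers were among them. Depth as the cause was argued against, since 863 of these genes (76.92%) were called again after every library was thinned to 4788541 counts. B cells and monocytes in the CD57-negative sort remain a candidate source for part of the pattern. Pairs of the 10 B cell markers rose and fell together within groups (median correlation 0.82 over 45 pairs, range 0.574 to 0.932, 20 libraries). MS4A1 and LYZ averaged 319 ± 229 and 408 ± 422 CPM in early canonical libraries. With the marker scores as covariates the lower genes kept 29.47% of their median fall (from -1.63 to -0.48) while the higher genes kept 61.6%. The 95% bootstrap interval of the first share, 25.8 to 34.0, came from drawing genes, not donors. Genes are not independent replicates, so it does not measure the spread between donors. Both sets were chosen by their calls without the covariates, so some loss is expected in any other fit. The median standard error of the lower genes went from 0.37 to 0.74 in the covariate fit, which is part of why no call was left. The CD56dim gate that the labels give would remove cells without CD56. A gate that excludes B cells and monocytes, which the labels do not mention, would also remove such cells, whose markers were on no other list. For the 13 early maturation genes the fall kept was 44.85% (interval over genes 7.68 to 107, from -2.03 to -0.91). B cells and monocytes cannot be told apart from maturation there because the interval is wide. Maturation itself stays open as the difference the design names.

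Late adaptive replicate 3 had 22841 genes with a read, against 15031 to 15612 in the others of its group. Its depth was argued against, since 21100 genes had a read after thinning to 4788541 counts, against 14287 to 16143 in the other 29 libraries. Cells of another type were argued against as well, since of its 11855 reads in genes silent in all other libraries the 10 highest genes held 2.531% and none exceeded 39 reads. Genomic DNA in the library is a candidate explanation: of 4642 genes with no read elsewhere 2405 had one here, and read number correlated across genes with exon length at rho = 0.5956 over the 3994 of them with a known length, where genes are not independent replicates. No biological explanation was tested.

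CD3E was higher in late adaptive than in late canonical NK cells by 3.02 ± 0.73 log2 units. T cells like the sorted effector memory CD8 cells were argued against as its source in the late adaptive sort. The difference would need 43.6% of their RNA, while CD8B allowed at most 6.203% and CD5 2.39%. Each bound came from the highest late adaptive library and the lowest effector memory library. T cells with little CD8B and CD5 RNA are not covered by these bounds, and gamma delta T cell markers were not analysed. CD3-negative gating would also remove T cells. The difference between adaptive and canonical cells that the design names stays open and was not tested further.

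Of 126 group values, 26 held a library apart from the others of its group by Dixon's ratio. Its critical value gives about 1 in 20 by chance only for independent, normally distributed values. These values are related to each other and many are skewed, so the 26 cannot be set against that rate. Total counts stood apart in replicate 3 of late adaptive (13388950), early canonical (16439818), effector memory (17171208) and naive cells (17074188), and genes with a read in late canonical replicate 3 (16289). T cell markers summed to 209 CPM in early canonical replicate 4 against 110 to 132 in the others, and CD8 markers to 31.3 CPM in early canonical replicate 5 against 107 to 133. B cell markers summed to 337 CPM in early adaptive replicate 3 against 9.66 to 98.1. Monocyte markers summed to 344 CPM in late canonical replicate 4 against 5.30 to 85.9, to 5220 in early adaptive replicate 4 against 8.53 to 1197, and to 92.7 in naive replicate 5 against 4.89 to 12.4. Erythroid and platelet markers summed to 20.9 CPM in late canonical replicate 4 and 197 in early adaptive replicate 3, and innate lymphoid markers to 71.2 in effector memory replicate 4. KLRC2 was at 92.1 CPM and CD3E at 273 in late canonical replicate 1, against 18.0 to 34.2 and 3.25 to 73.6. CD3E was at 1320 CPM and FCER1G at 54.7 in naive replicate 1, and CD8A at 30.1 in early canonical replicate 5. CD4 was at 3.84 CPM in late adaptive, 6.21 in late canonical and 36.1 in early canonical replicate 4, CD5 at 5.59 and 36.6 in the latter pair of libraries, and ALPK2 at 3.18 in naive replicate 4.

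The test of the late minus early difference of the adaptive effect was passed by ALPK2 (5.38) and by the late maturation (median -0.51), effector T cell (-0.49) and KIR lists (-1.28). With the marker scores as covariates ALPK2 (6.15, adjusted p = 0.070) and the KIR list (median -0.62, camera adjusted p = 0.16) did not pass, and the late maturation and effector lists (medians -0.83 and -0.61) lost their calls with an estimated correlation (adjusted p = 0.45 in each).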

How the results depend on the processing

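The marker-score covariates, leaving out late adaptive replicate 3 or early adaptive replicate 4, and thinning were chosen after seeing the data. In the following, counts of changed genes are given against 651 (late adaptive against late canonical), 943 (early adaptive against early canonical), 1874 (late against early canonical), 272 (late against early adaptive), 3383 (late adaptive against early canonical), 4484 (effector memory against naive) and 1 (dependence of the adaptive difference on stage). With no replicate block, which ignores the pairing by donor, the NK counts were 9, 22, 243, 3, 849 and, for stage, 0. Leaving out each donor gave 153 to 890, 349 to 936, 1016 to 1564, 7 to 678 and, for stage, 0 to 3, so some counts went up with fewer libraries. Fitting all 30 libraries gave 295, 383 and, for stage, 2, in the late adaptive, early adaptive and stage comparisons. Fitting only the 2 groups compared gave 284 for the early adaptive comparison and 1951 for late adaptive against early canonical. DESeq2 called 1106 genes (late adaptive against canonical), 829 (late against early adaptive) and 67 (stage), and limma-voom 50 and 0 for the latter pair. For late against early adaptive cells no low-count filter gave 150 and log2(FPKM + 1) 151. For stage, log2(FPKM + 0.1) gave 0 with and without a filter, log2(FPKM + 1) 3 and thinning 0. Without late adaptive replicate 3 the counts were 372, 123 (late against early adaptive) and 0 (stage), and without early adaptive replicate 4 they were 65 and 2 in the latter pair, and 1939 for late against early canonical cells. With marker-score covariates they were 0 for early adaptive and for late canonical against early canonical cells (edgeR, 2294 and 1555 at an unadjusted p under 0.05), 3 for late against early adaptive and 6 for late adaptive against early canonical. An adjusted p under 0.01 gave 209, 291, 815, 41, 1880, 1938 and 0, and a log2 fold change of at least 1 gave 263, 315, 824, 1265 (late adaptive against early canonical) and 1985 (T cells), fewer by construction. The correlation of NK and T cell fold changes, 0.458 across genes, was 0.1299 with no low-count filter, 0.4454 to 0.4664 without each donor, 0.1501 and 0.4349 with the late adaptive minus late canonical and the late minus early canonical contrasts, and 0.3103 as Spearman's rho. Where not given by construction, the cause was not tested.

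Lists and named genes turned, meaning a change of direction with a call in either fit, only with the marker-score covariates. Without a call in either fit, directions also changed under other settings, for 17 of 199 list results without donor 5. For named genes 5 such values were found over all settings. Over all called genes, the covariate fit turned the sign of 69 of 943, 398 of 1874 and 789 of 3383 in the early adaptive, late against early canonical and late adaptive against early canonical comparisons. On FPKM values 1 to 3 changed sign in each of the late against early canonical, late adaptive against early canonical and T cell comparisons. Camera adjusted p of lists that turned was 0.08391 (sterol), 0.2312 (heat shock), 0.9635 (proximal signalling) and 0.01487 (HLA class II) for early adaptive against early canonical cells. For late against early canonical it was 7.646e-12 (respiratory chain), 4.522e-05 (glycolysis), 0.03087 (sterol), 0.7585 (immediate early), 0.1516 (heat shock), 0.8956 (B cell) and 0.8682 (monocyte). For late against early adaptive it was 3.723e-06 (respiratory chain), 0.03771 (sterol) and 0.8564 (monocyte). For late adaptive against early canonical it was 9.679e-05 (glycolysis), 0.04153 (sterol), 0.9567 (immediate early), 0.1264 (heat shock and HLA class II) and 0.9276 (monocyte), and for stage 0.145 (sterol), 0.2524 (heat shock) and 0.7395 (B cell). Genes that turned were HDAC9 (0.93), CD79A (1.03) and HMGCS1 (0.11) in the early adaptive comparison and S1PR5 (-0.018), CD27 (0.25) and CD22 (0.21) in late against early canonical. The covariates are the mean log2 CPM of the B cell and monocyte lists, so the mean change of those lists, which hold CD79A and CD22, is removed by construction. For the other lists and genes the cause was not tested. Of 199 list results, 75 lost their call with an estimated correlation, and 198 kept direction and side of the threshold with DESeq2-type size factors. Of 5273 values of 264 named gene results under alternatives, 4292 kept direction and side of the threshold, 961 lost the call and 6 turned. No scaling moved the median of all genes by over 0.1. After every library was thinned to 4788541 counts, 545 of the 651 and 3873 of the 4484 genes were called again.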

Other observations

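The covariance of NK and T cell fold changes, the zinc finger test, the values for independent lists and the genes named in the next paragraph were chosen only after values had been seen.

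Of the 140 genes higher in adaptive than canonical cells at both CD57 stages, 136 were tested in T cells, and 78 of these were also higher in effector memory than naive cells (24.6 for independent lists) while 16 were lower (24.1). Of the 78, 12 were on a fixed list. Among the 78, with log2 fold changes in late NK, early NK and T cells, were the adhesion molecule CADM1 (2.23, 3.15 and 3.83), SGCD (1.90, 3.75 and 4.38), ZNF365 (2.98, 3.08 and 3.31), the secreted factor PROK2 (3.79, 6.70 and 5.24), the calcineurin regulator RCAN2 (3.69, 5.83 and 3.90) and the condensin subunit NCAPH (2.48, 2.93 and 2.44). Of the 105 genes lower at both stages, 91 were tested in T cells, and 37 were also lower in effector memory cells (16.1 for independent lists) while 11 were higher (16.5). Of the 37, 2 were on a fixed list. Among the 37 were TBC1D4, a regulator of glucose transporter traffic (-1.74, -1.72 and -3.30), AEBP1 (-3.07, -1.87 and -5.05) and the growth factor receptor IGF1R (-0.98, -0.76 and -1.97). PROK2 and ZNF365 in both NK comparisons, RCAN2 in the early and AEBP1 in the late one were outside the ranked naming rule. They averaged under 5 CPM or did not move 1 way in all donors. RCAN2 averaged 0.107 ± 0.206 CPM in early canonical cells, and fold changes from such levels are uncertain. No library entered both an NK and the T cell comparison, but the donors were the same.

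Other splits of the same libraries, drawn at random, were fitted for each count of changed genes. Only the real split, 1 of 40, gave as many genes for late adaptive against late canonical cells (651 genes, highest other 200), early adaptive against early canonical (943, highest other 1), late against early canonical (1874, highest other 80), late against early adaptive (272, highest other 9) and late adaptive against early canonical (3383, highest other 4). For effector memory against naive T cells it was 1 of 80 (4484, highest other 1527). For the count of 1 gene in the test of dependence on stage it was 2 of 40. The highest other count, 9, came from 1 split that parted 3 donors, and its cause was not tested. The rule written beforehand took a share under 0.05 of all drawn splits as arguing against chance. It was set aside after the values had been seen. By that rule the count for stage would have been read as chance, and the other counts would not. These draws do not decide about chance, because the libraries are paired by donor and most drawn splits part only 1 or 3 donors. Such splits compare fewer pairs than the real one. Only 16 splits, the real one included, part all 5 donors, too few for a share under 0.05. The highest other counts among them were 200, 89, 0, 1, 12 and 0 in the same order, and 0 for the dependence on stage. They mix the groups across donors, unlike the real split.

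With the NK fold changes held fixed, 23 of 80 splits of the T cell libraries gave a correlation across genes as far from 0 as the real 0.458 (highest other 0.5238). A covariance as far from 0 as 0.328 came from 20 of 80 (highest other 0.5024). By the rule written beforehand the share for the correlation would have been read as chance. That rule was set aside here too, after the values had been seen. These shares decide nothing about chance, since a split that parts 1 or 3 donors keeps those donors' own difference between effector memory and naive cells. Among the 16 splits that part all 5 donors, 6 gave a correlation as far from 0, the real one included (highest other 0.488). The real correlation therefore did not stand apart from theirs. For the covariance only the real split, 1 of 16, did so (highest other 0.278). These splits are too few for a share under 0.05.

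Zinc finger genes, taken by the symbols ZNF, ZSCAN and ZKSCAN, may be lower as a group in adaptive NK cells. The family was picked because members were noticed among the shared lower genes, so the same comparisons are not an independent test of it. Of 502 tested, 33 fell and 4 rose in late adaptive against late canonical cells (6.57% fell, against 2.63% of other genes), and 26 fell and 4 rose in the early comparison (5.18% against 3.24%). The medians were -0.04 and -0.07, and camera p, not adjusted over lists, was 0.0118 and 0.00472 with the preset correlation but 0.1383 and 0.10 with an estimated one, so the hypothesis stays open. In T cells 80 of 490 fell and 58 rose, and the share that fell was below that of other genes (16.3% against 18.6%, camera p = 0.35, p = 0.39 with an estimated correlation).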
